A study of Mus musculus with 6 samples.

How the data were processed

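Polyadenylated RNA was measured by bulk sequencing in left ventricles of 6 mice, 3 with a global deletion of cytoglobin (Cygb, a globin found in fibroblasts and vascular wall cells) and 3 wild-type littermates. Each mouse had received angiotensin II, a pressor hormone, at 1.5 mg/kg/day for 2 weeks from an osmotic pump under the skin. Per the labels, each library came from an individual mouse, so the spread between libraries of a group includes the spread between animals. No mouse without angiotensin II was used here.

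The authors deposited 1 table of raw, whole-number counts per gene for the 6 libraries, with gene identifiers and symbols. The submitters' processing notes name the mm10 build and DESeq2, with no versions; the aligner, the counter, the annotation and any use of strand are not given in the sources used here. The table held 13384 genes, and each had more than 0.5 CPM (counts scaled to the library total) in every library. A filter that left out genes low in any one library would give such a table, but none is given in the sources used here; a gene silenced in one group would be lost to it. Cygb was not analysed here, so neither its fold change nor the check of the genotype labels by the targeted gene is given. The table named 170 genes by identifier alone. Library totals were taken from this table, and they ran from 23190864 to 30354857 counts. Every library had at least 12 counts for every gene, and the common biological coefficient of variation was 0.166. Counting error was the larger part for genes near that floor, and the spread between animals for abundant genes.

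Counts were fitted in edgeR 4.0.16 (R 4.3.3) by the quasi-likelihood test with robust estimation, TMM size factors and the tool's own filter on low counts, which removed 0% of the genes. The 3 knockout libraries were compared with the 3 wild-type libraries without covariates. Tests were two-sided, and p-values were adjusted by Benjamini-Hochberg over all 13384 genes with a threshold of 0.05. Log2 fold changes are knockout minus wild type, standard errors come from the test statistic, and levels are TMM-scaled CPM, given as mean ± SD. Before the data were examined, 46 lists of genes were fixed for the tissue and treatment, and Cygb was kept out of them. Lists with at least 3 measured genes, except a list of sex-linked genes kept as a check of the animals, were tested by camera in limma 3.58.1 on voom values with a preset correlation of 0.01, adjusted over the 43 lists tested. The same lists were tested with the correlation estimated from the data and by fry. The number of members past 0.05 was counted after adjustment over all genes and after adjustment over the list alone. The latter does not correct across lists. As 2597 of all 13384 genes had an unadjusted edgeR p under 0.05, a count over the list alone is not by itself particular to its list. The symbols of the mitochondrially encoded genes were matched to the table's own symbols after the table was seen.

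Genes were named by a rule set before the data were examined. It took Cygb first. Among genes past the threshold with non-overlapping groups, a mean of at least 1 CPM and a conventional name, it then took the 10 largest rises and the 10 largest falls, and, where fewer than 5 qualified in a direction, the 5 smallest p-values in that direction. It further took up to 4 members of each list with the smallest p-values, and 10 genes of the natriuretic peptide, myosin, actin and matrix groups whatever their result. Not every gene that the rule takes is named or given a value in the text, and 2 of them are not reported here; all but Cygb, which was not analysed here, are included in the counts. Genes outside the rule are said to have been chosen after their values were seen.

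On simulated counts for the 13384 genes with 200 genes changed, in 5 simulations of this comparison, edgeR recovered 14.3% of genes changed by a log2 of 0.5, 76.1% of those changed by 1 and 97.9% of those changed by 2, and 6.86% of its calls were false. DESeq2 1.42.0 recovered 25.7%, 80.9% and 97.0%, with 13.1% of calls false. Camera called 100% of the shifted lists and 0% of the unshifted ones. The simulated genes varied independently, so the camera check says nothing about correlated genes. The simulated libraries also had no GC content trend and no outlying library, so the rates for edgeR and DESeq2 need not hold for these data.

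The alternatives fixed before the data were examined were RLE and upper quartile size factors, other filters on low counts, DESeq2, limma-voom, estimation without robustness, other thresholds, the replicate number as a block and each library left out in turn. Chosen after seeing the data were a correction of each library's trend on GC content and transcript length (splines with 4 degrees of freedom), a fit without the genes of the mitochondrial chromosome, and edgeR's older quasi-likelihood method. GC content and length came from GENCODE M21 transcripts and were found for 94.2% of the genes. Coordinates are from the RefSeq annotation of GRCm38.p6, the assembly of mm10, in which 98.3% of the gene identifiers were found. No 2 libraries of a group agreed within sampling noise (chi-square per degree of freedom from 21.6 to 58.9), so all 6 were counted. Plots were drawn with matplotlib.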

Results

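Left ventricles were compared between 3 cytoglobin knockout mice and 3 wild-type littermates, all infused with angiotensin II for 2 weeks. The aim was to find the transcripts that differ between the genotypes in a heart under this stress. Whether such a difference follows from the loss of cytoglobin itself was not tested. The knockout libraries held 25002634, 23190864 and 23652385 counts in replicates 1, 2 and 3, and the wild-type libraries 24725110, 24791227 and 30354857. Cygb was not analysed here, so the genotype was taken from the labels. The Y-linked genes Uty, Ddx3y, Kdm5d and Eif2s3y were measured in all 6 libraries. Ddx3y ran from 47.2 to 102 CPM and Eif2s3y from 47.2 to 67.9 CPM over the libraries, so none came from an animal without a Y chromosome. None of the 4 passed the test over all genes, and all 4 were higher in the knockout when adjusted over the list alone (median log2 fold change 0.45, and 0.16 after removal of the GC content and length trend).

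Knockout ventricles had less transcript of Acta1, which encodes skeletal alpha-actin and is a gene of the fetal and hypertrophic heart. Acta1 was 2.45-fold lower, at 728 ± 59.4 CPM in the knockout and 1780 ± 173 CPM in the wild type (log2 fold change -1.29, SE 0.13, edgeR adjusted p = 0.00304; n = 3 each). Dact3 (-1.43, SE 0.17, edgeR adjusted p = 0.00726) and the WNT receptor gene Fzd2 (-1.25, SE 0.20, edgeR adjusted p = 0.0361) also fell. Acta1 passed without any one library except knockout replicate 3 (edgeR adjusted p = 0.0562, the highest of its 17 alternatives), and Dact3 except knockout replicates 1 (0.0538) and 3 (0.0680, its highest). Fzd2 passed in 12 of 17 alternatives (edgeR adjusted p up to 0.194). Among the genes that rose, Ppp1r3a, which encodes a glycogen-targeting subunit of protein phosphatase 1, was at 213 ± 36.2 CPM against 97.0 ± 17.2 CPM (log2 fold change 1.14, SE 0.16). Lnpep, the aminopeptidase that binds angiotensin IV, was at 60.4 ± 14.2 CPM against 26.9 ± 5.10 CPM (1.17, SE 0.19).

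In all, 12 genes rose and 3 fell among 13384 in edgeR's quasi-likelihood test. Other rises were those of the zinc-finger genes Zfp369 (1.89, SE 0.31), Zfp968 (1.40, SE 0.22) and Zfp970 (1.19, SE 0.15) and of Ide, which encodes insulin-degrading enzyme (1.13, SE 0.17). They also included the interferon-induced GTPase gene Iigp1 (1.02, SE 0.16), Btaf1 (1.00, SE 0.16) and Ppip5k2 (1.00, SE 0.14). The edgeR adjusted p-values of these 9 rises lay between 0.0137 and 0.0394. With upper quartile size factors 8 genes rose and 3 fell, without Zfp369, Lnpep and Iigp1. Cxcl14, a chemokine gene (0.99, SE 0.15), also rose, as did Phkg1, a phosphorylase kinase subunit gene (0.99, SE 0.15), which was named after its values were seen. Zfp968 and Zfp970 belong to a cluster of closely related zinc-finger genes on chromosome 2, where the authors' counting could split reads between copies, so their values are uncertain. Next among the lower genes by p-value, Otulin (-0.80, SE 0.14, edgeR adjusted p = 0.0533) and Msrb3 (-0.75, SE 0.14, edgeR adjusted p = 0.0565) did not pass. The 2597 genes at an unadjusted p under 0.05, 1381 of them higher and 1216 lower, compare with 669 given by chance. Groups did not overlap for 22.3% of genes, against 10% by chance. Both chance figures leave out any trend shared by many genes, such as that on GC content given below. DESeq2 called 352 genes higher and 266 lower, the 15 edgeR calls among them. The counts rested on single libraries: rises and falls numbered 0 and 1 without knockout replicate 1, 11 and 4 without knockout replicate 2, 0 and 0 without knockout replicate 3, 3 and 5 without wild-type replicate 1, 982 and 869 without wild-type replicate 2, and 7 and 10 without wild-type replicate 3.

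**Figure D1:**
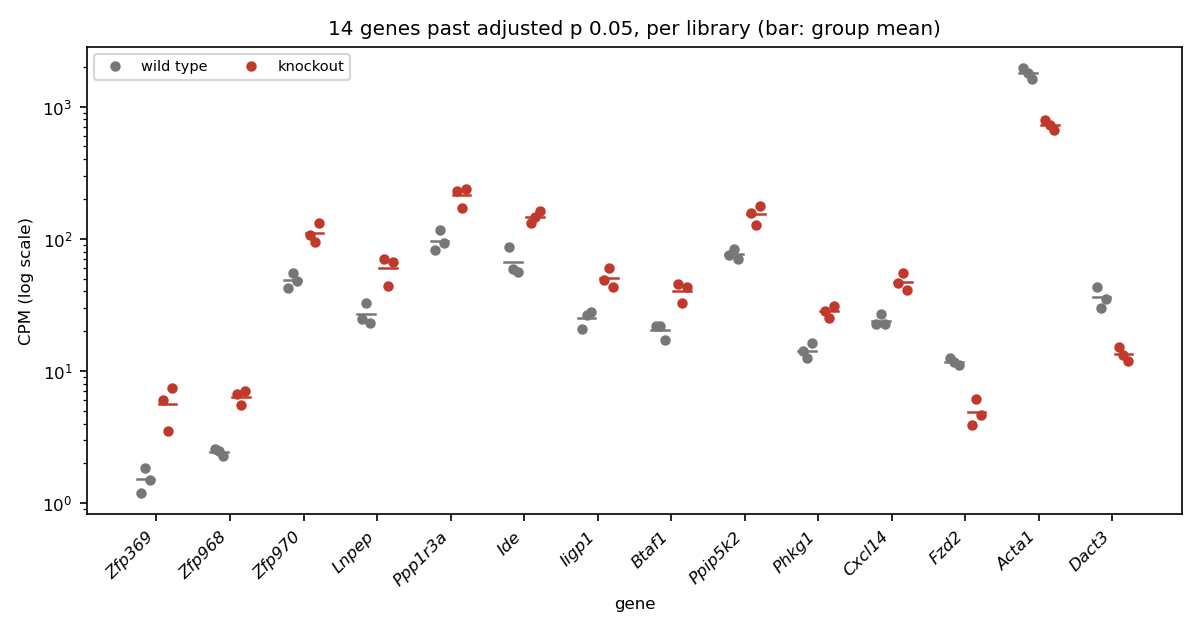
Levels of 14 genes past the edgeR threshold in each of the 6 libraries, in CPM on a log scale, with points for libraries and bars for group means. No knockout library overlaps a wild-type library for any of them, which the naming rule required of the rises it took by size. Over all genes, groups did not overlap for 22.3%. Acta1 has a mean of 728 CPM in the knockout against 1780 CPM in the wild type.

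In GRCm38, Acta1 lies on chromosome 8 from 123891758 to 123894775, Dact3 on chromosome 7 from 16875317 to 16887301 and Fzd2 on chromosome 11 from 102604431 to 102608058. Ppp1r3a lies on chromosome 6 from 14713822 to 14755274, Lnpep on chromosome 17 from 17527723 to 17624489 and Iigp1 on chromosome 18 from 60373616 to 60392634. Btaf1, from 36926079 to 37014057, and Ide, from 37268743 to 37334544, are close to each other on chromosome 19. All are protein-coding genes, and each value covers the reads the authors assigned to the whole gene.

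The list of hypertrophy and fetal cardiac genes was lower in the knockout, with 18 of 21 measured members below 0 and a median log2 fold change of -0.34 (camera adjusted p = 0.000152; adjusted p = 0.502 with an estimated correlation). Acta1 was its 1 member to fall over all genes, and 4 members fell and 1 rose when adjusted over the list alone. The calcineurin target Rcan1 (-0.99, SE 0.26) and the transcription factor gene Gata4 (-0.54, SE 0.18) were among those 4, and Myocd (0.53, SE 0.16) was the 1 higher. Gata4 was at -0.30 without wild-type replicate 1. The list's median was -0.19 without wild-type replicate 2 (camera adjusted p = 0.0233) and -0.51 without knockout replicate 2 (1.44e-05). The natriuretic peptide genes did not pass. Nppa was at 496 ± 42.8 CPM against 1655 ± 900 CPM (log2 fold change -1.74, SE 0.50, edgeR adjusted p = 0.169). Nppb was at 430.2 ± 196 CPM against 915 ± 292 CPM (-1.09, SE 0.39, edgeR adjusted p = 0.211). Nppa was at 2282, 2058 and 623 CPM in wild-type replicates 1, 2 and 3, and without replicate 3 it passed the edgeR test (adjusted p = 7.63e-05, the lowest of 17 alternatives that reached 0.515). Neither Myh6 (-0.051, SE 0.19, edgeR adjusted p = 0.907) nor Myh7 (-0.29, SE 0.27, edgeR adjusted p = 0.595), the adult and fetal myosin heavy chain genes, differed beyond the spread between replicates. Myh7 was at -0.53 without knockout replicate 2 and -0.027 without knockout replicate 1. Markers of atrial muscle stood apart in wild-type replicate 1, with Myl7 at 249.6 CPM against 12.05 to 27.6 CPM in the other 5 libraries and Myl4 at 391.7 CPM against 16.5 to 36.2 CPM. Sln was at 112 CPM there against 4.08 to 11.8 CPM. Nppa was also highest in that library, and how much of it came from atrial muscle was not tested. The atrial list as a whole did not pass, with a median of -0.95 over 9 genes (camera adjusted p = 0.0519). Without wild-type replicate 1 its median was -0.29 (camera adjusted p = 0.145), and it passed without wild-type replicate 2 (0.0185), wild-type replicate 3 (0.0142) or knockout replicate 3 (0.0213). No member passed over all genes or adjusted over the list alone. Its members of smallest p were Nr2f1, Myl7, Myl4 and Sln.

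Genes of activated fibroblasts and of the extracellular matrix were lower in the knockout. The activated fibroblast list had a median log2 fold change of -0.78, with 27 of 31 measured members below 0 (camera adjusted p = 3.14e-05; adjusted p = 0.538 with an estimated correlation). None of them passed over all genes, and 6 fell when adjusted over the list alone, among them Fbln2 (-0.67, SE 0.13), the homeobox gene Meox1 (-1.03, SE 0.20), the crosslinking enzyme gene Loxl1 (-0.79, SE 0.17) and Ccn2 (-0.98, SE 0.27). For collagens, 18 of 19 were below 0 with a median of -0.40 (camera adjusted p = 3.14e-05; adjusted p = 0.524 with an estimated correlation). No collagen passed over all genes and 7 fell when adjusted over the list alone, including Col7a1, Col5a3 (-1.07, SE 0.30), Col6a1 (-0.40, SE 0.12) and Col16a1. Non-collagen matrix genes had a median of -0.27 over 40 (camera adjusted p = 0.000938; adjusted p = 0.538 with an estimated correlation). Over all genes, no member passed, and 4, Prelp, Emilin1, Pcolce and Bgn, were lower when adjusted over the list alone. Wild-type replicate 2 stood apart in this group of genes. Postn was at 542 CPM there, against 97.8 and 123 CPM in the other wild-type libraries and 104 to 172 CPM in the knockout. Without that library the medians were -0.11 for activated fibroblasts (camera adjusted p = 0.166), -0.15 for collagens (camera adjusted p = 0.110) and -0.12 for the other matrix genes (camera adjusted p = 0.322).

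The single matrix genes named in advance did not pass either. Postn, which encodes periostin, had a log2 fold change of -0.78 (SE 0.80, edgeR adjusted p = 0.636), Col1a1 -0.58 (SE 0.27, edgeR adjusted p = 0.278), Col3a1 -0.30 (SE 0.41, edgeR adjusted p = 0.725) and Fn1 -0.0060 (SE 0.19, edgeR adjusted p = 0.990). Without wild-type replicate 2, Postn was at 0.43, Col3a1 at 0.29 and Col1a1 at -0.24. Acta2, the smooth muscle actin gene of myofibroblasts and of smooth muscle cells, was at 67.3 ± 9.31 CPM against 114 ± 23.8 CPM (-0.75, SE 0.16, edgeR adjusted p = 0.0656). Without wild-type replicate 2 it passed the edgeR test (adjusted p = 0.00972, in a range of 0.00218 to 0.320 over 17 alternatives). In that fit 1851 genes passed, so the pass was not particular to Acta2.

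Targets of TGF-beta and BMP signalling were lower, with a median log2 fold change of -0.43 over 24 genes (camera adjusted p = 0.000152; adjusted p = 0.328 with an estimated correlation). No member passed over all genes and 9 fell when adjusted over the list alone, among them Ltbp3, Tgif1, Pmepa1 (-0.62, SE 0.16) and the inhibitory SMAD gene Smad7 (-0.60, SE 0.16). The WNT list had a median of -0.34 over 20 genes (camera adjusted p = 0.00267; adjusted p = 0.328 with an estimated correlation). Fzd2 fell over all genes. Adjusted over the list alone, 4 members fell, with Fzd2, the ligand gene Wnt5b (-1.44, SE 0.29) and Dkk3 (-1.54, SE 0.36) among them, and Fzd4 rose (0.82, SE 0.18). Both lists also passed without any one wild-type library.

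Markers of mural and mesenchymal cells were lower as well. Fibroblast identity genes had a median of -0.23 over 19 (camera adjusted p = 0.00286; adjusted p = 0.502 with an estimated correlation). Over all genes none passed. Adjusted over the list alone, 9 were lower, including Pi16, Gsn, Htra3 and Tcf21, and 1 was higher. Without wild-type replicate 2 the identity list did not pass (camera adjusted p = 0.133). Smooth muscle genes had a median of -0.24 over 13 (camera adjusted p = 0.00410; adjusted p = 0.524 with an estimated correlation). None of them passed over all genes, and 4, Tpm2, Acta2, Ckb and Myl9, were lower when adjusted over the list alone. Without wild-type replicate 1 the smooth muscle list did not pass (camera adjusted p = 0.0821), and its median was -0.52 without wild-type replicate 3 (5.55e-05) and -0.46 without knockout replicate 2 (0.00306). Pericyte genes had a median of -0.33 over 12 (camera adjusted p = 0.0140; adjusted p = 0.507 with an estimated correlation). Over all genes none passed. Adjusted over the list alone, 6 were lower, among them Kcnj8, Ndufa4l2, Cspg4 and Vtn, and 1 was higher. The 5 measured mesothelial genes had a median of -1.03 (camera adjusted p = 0.0171; adjusted p = 0.524 with an estimated correlation). Over all genes, no member passed, and Msln, Gpm6a and Upk3b were lower when adjusted over the list alone, unlike Aldh1a2. Upk3b and Msln were highest in wild-type replicate 1, at 19.5 and 11.6 CPM against 1.46 to 7.40 CPM and 2.07 to 5.78 CPM in the other libraries. Without wild-type replicate 2 the mesothelial list did not pass (camera adjusted p = 0.0660). Globin genes, expressed in red blood cells, had a median of -0.41 over 6 (camera adjusted p = 0.0168; adjusted p = 0.524 with an estimated correlation). No globin passed over all genes or adjusted over the list alone. Hba-a1 and Hba-a2 are near-identical copies, as are Hbb-bs and Hbb-b1, so their separate values are uncertain. Without wild-type replicate 1 the globin list had a median of -0.19 and did not pass (camera adjusted p = 0.145).

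**Figure D2:**
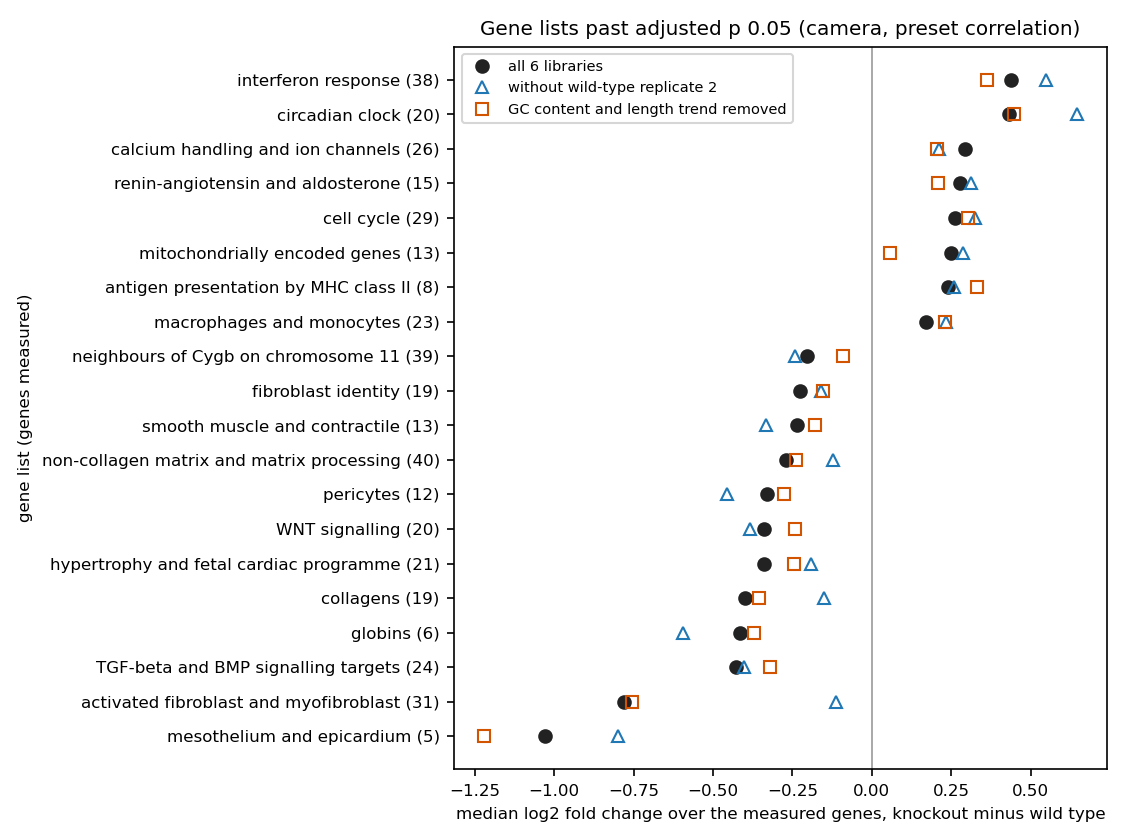
Median log2 fold change, knockout minus wild type, over the measured genes of the 20 lists past the camera threshold, with filled circles for all 6 libraries, triangles without wild-type replicate 2 and squares after removal of the GC content and length trend. The activated fibroblast median moves from -0.78 to -0.11 without wild-type replicate 2, and the mitochondrially encoded median from 0.25 to 0.056 after the trend is removed.

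Interferon response genes were the list of smallest camera p among those higher in the knockout. Of 38 measured members 36 were above 0, with a median log2 fold change of 0.44 (camera adjusted p = 9.03e-10; adjusted p = 0.502 with an estimated correlation). Iigp1 rose over all genes and 14 members rose when adjusted over the list alone, among them the GTPase genes Igtp (0.82, SE 0.18), Gbp7 (0.68, SE 0.15) and Gbp3 (0.72, SE 0.16). Genes of MHC class II presentation, all 8 above 0, had a median of 0.24 (camera adjusted p = 0.0277; adjusted p = 0.538 with an estimated correlation). No member passed over all genes, and H2-DMa (0.82, SE 0.24) was higher when adjusted over the list alone. H2-DMb1, H2-Eb1 and H2-Aa followed by p-value. Macrophage and monocyte markers had a median of 0.17 over 23 (camera adjusted p = 0.0426; adjusted p = 0.524 with an estimated correlation). None of them passed over all genes, and the scavenger receptor gene Cd163 (0.91, SE 0.17) was higher when adjusted over the list alone. F13a1, Mrc1 and Cx3cr1 followed, the last at -0.69 (SE 0.27). Cx3cr1 was at -1.09 without knockout replicate 2 and -0.43 without knockout replicate 3. The MHC class II list did not pass without wild-type replicate 1 (camera adjusted p = 0.181), wild-type replicate 2 (0.132) or knockout replicate 2 (0.182). Its median was 0.13 without wild-type replicate 1, 0.16 without knockout replicate 2 and 0.39 without wild-type replicate 3 (0.000165). The macrophage list did not pass without wild-type replicate 1 (0.243), wild-type replicate 3 (0.0525) or knockout replicate 2 (0.118).

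Several groups of heart muscle and proliferation genes were also higher. Calcium handling and ion channel genes had a median of 0.29 over 26 (camera adjusted p = 0.000973; adjusted p = 0.502 with an estimated correlation). Over all genes, no member passed, and 8 were higher when adjusted over the list alone, including Kcnd2, Cacna2d1 (0.79, SE 0.17), the ryanodine receptor gene Ryr2 (0.70, SE 0.16) and Kcna5. Without knockout replicate 3 the median was 0.18 (camera adjusted p = 0.00256). The renin-angiotensin list had a median of 0.28 over 15 (camera adjusted p = 0.00195; adjusted p = 0.328 with an estimated correlation). Lnpep rose over all genes, and 4 members, with the mineralocorticoid receptor gene Nr3c2 (0.71, SE 0.20), Rgs2 and Mme, rose when adjusted over the list alone. Cell cycle genes had a median of 0.26 over 29 (camera adjusted p = 0.00251; adjusted p = 0.538 with an estimated correlation). No member passed over all genes, and 3, Cenpf (1.71, SE 0.31), Top2a (1.28, SE 0.29) and Mki67 (0.83, SE 0.23), were higher when adjusted over the list alone. Prc1 was at 0.89 (SE 0.30), and ran from 0.53 to 1.12 over 17 alternatives. Without knockout replicate 2 the cell cycle list did not pass (camera adjusted p = 0.0525). The 13 mitochondrially encoded genes were all above 0 with a median of 0.25 (camera adjusted p = 0.000152; adjusted p = 0.524 with an estimated correlation). None of them passed over all genes, and ATP8, ND5 and ND4L, but not ND2, were higher when adjusted over the list alone. Genes of the mitochondrial chromosome took 24.0%, 20.4% and 23.4% of counts in the knockout libraries and 18.2%, 19.7% and 19.96% in the wild-type libraries.

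Circadian clock genes had a median of 0.43 over 20 (camera adjusted p = 0.0136; adjusted p = 0.502 with an estimated correlation). Over all genes, no member passed, and the transcription factor genes Hlf (0.98, SE 0.20) and Rora (0.94, SE 0.22) were higher when adjusted over the list alone. Usp2 and Tef followed. Wild-type replicate 1 stood apart here too, with Per1 at 11.98 CPM against 44.2 to 118 CPM in the other libraries. Dbp was at 5.06 CPM against 43.5 to 100.4 CPM, and Nfil3 at 49.98 CPM against 8.49 to 12.7 CPM. Per1, Dbp and Nfil3 were chosen after their values were seen. The clock list also passed without any one library (median 0.37 and camera adjusted p = 0.0448 without wild-type replicate 1). The list of 39 measured genes near Cygb on chromosome 11 had a median of -0.21 (camera adjusted p = 0.00172; adjusted p = 0.524 with an estimated correlation). No member passed over all genes, and 5, among them St6galnac2 (-0.98, SE 0.19), Trim47, Mxra7 and Rhbdf2, were lower when adjusted over the list alone.

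**Figure D3:**
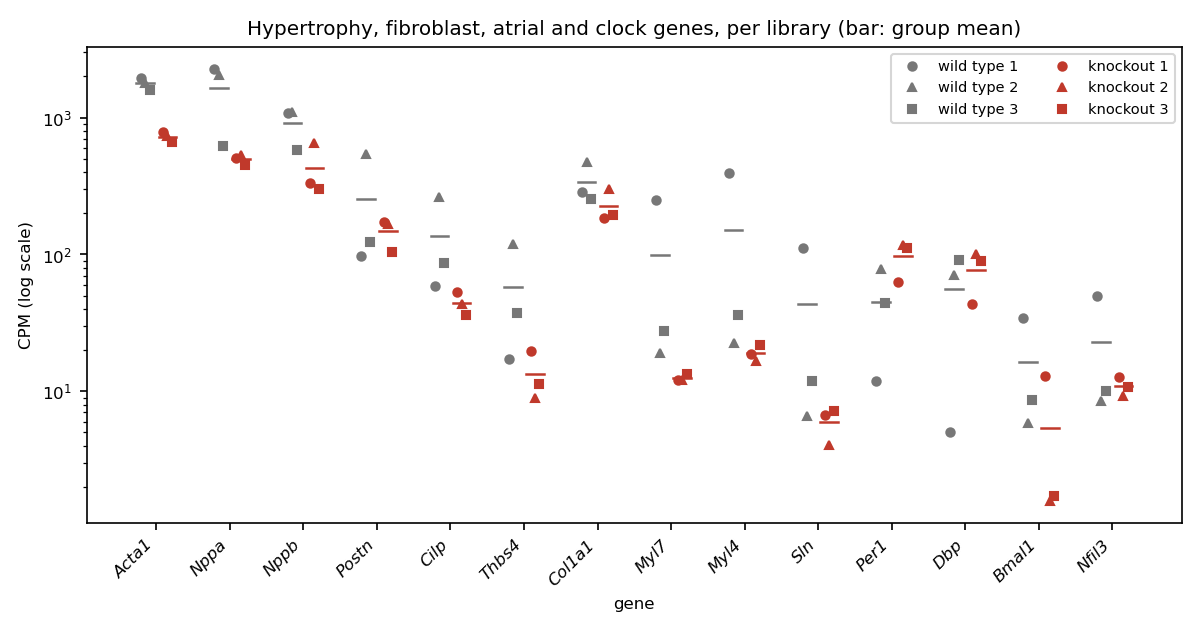
Levels of hypertrophy, fibroblast, atrial and clock genes in each library, in CPM on a log scale, with a symbol per replicate number and bars for group means; Cilp, Thbs4 and the clock genes were chosen after their values were seen. Wild-type replicate 1 has the highest Myl7 (249.6 CPM) and the lowest Dbp (5.06 CPM), and wild-type replicate 2 the highest Postn (542 CPM).

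Camera called 20 of the 43 lists, 8 higher and 12 lower. None passed with an estimated correlation or by fry, whose smallest adjusted p was 0.0705. With the preset correlation, groupings of the libraries that mixed the genotypes called 10 to 21 lists. The number of lists called is therefore not particular to the genotypes. Across genes, which are not independent replicates, the log2 fold change had a Spearman correlation of -0.53 with GC content and 0.35 with transcript length. After that trend was removed 16 of the 20 lists passed. The mitochondrially encoded genes (camera adjusted p = 0.213), the genes near Cygb (0.235), fibroblast identity (0.0759) and globins (0.166) did not.

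The other 23 lists did not pass camera, and in all of them but cytokines no member passed over all genes. Besides the atrial list, 4 of them passed when 1 library was left out. Ribosomal protein genes passed without wild-type replicate 1 (median -0.18, camera adjusted p = 0.00201), and nitric oxide and cyclic GMP genes without wild-type replicate 3 (-0.21, 0.0442). Oxidative phosphorylation genes passed without wild-type replicate 2 (-0.13, 0.0246) or knockout replicate 1 (-0.13, 0.0313). Immediate early genes passed without knockout replicate 2, with a median of -0.23 (0.0183) against 0.026 with all libraries. Cytokine and chemokine genes had a median of 0.071 over 19 (camera adjusted p = 0.425). Cxcl14 rose over all genes, and adjusted over the list alone Cxcl14 and Ccl11 were higher and Cx3cl1 lower, with Icam1 next. Nitric oxide and cyclic GMP genes had a median of -0.15 over 20 (camera adjusted p = 0.104), with 3 higher and 3 lower when adjusted over the list alone. Cyb5r3, a reductase gene (-0.80, SE 0.15), Npr3 and Ddah2 were lower and the kinase gene Prkg1 (0.75, SE 0.17) higher. Endothelial genes had a median of -0.056 over 18 (camera adjusted p = 0.464), with Aqp1 (0.52, SE 0.12) higher and Egfl7 (-0.60, SE 0.16) lower when adjusted over the list alone, ahead of Eng and Kdr. Genes of p53, senescence and cell death had a median of -0.037 over 25 (camera adjusted p = 0.883), with 2 higher, Sesn1 and Fas, and 3 lower, Phlda3 (-0.74, SE 0.14) and Bbc3 among them, adjusted over the list alone.

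Among metabolic and stress lists, glycolysis genes had a median of -0.092 over 23 (camera adjusted p = 0.308), with Pfkfb1 (1.50, SE 0.26) higher when adjusted over the list alone, ahead of Pfkl, Pfkfb3 and Pgam1. Fatty acid oxidation genes had a median of -0.035 over 32 (camera adjusted p = 0.719), with the nuclear receptor gene Ppara (0.61, SE 0.15) higher when adjusted over the list alone, ahead of Acot2, Ppargc1a and Acot1. Antioxidant genes had a median of -0.0032 over 37 (camera adjusted p = 0.719), with the extracellular enzyme genes Sod3 (-0.55, SE 0.13) and Gpx3 (-0.61, SE 0.16) lower when adjusted over the list alone, ahead of Nfe2l2 and Txnrd2. Immediate early genes had a median of 0.026 over 22 (camera adjusted p = 0.764), with Nr4a3 (1.01, SE 0.27) higher and Jund (-0.91, SE 0.25) lower when adjusted over the list alone, ahead of Klf6 and Fosl2. Right ventricle, septum and conduction genes had a median of -0.083 over 11 (camera adjusted p = 0.764), with the potassium channel subunit gene Kcne1 (-1.46, SE 0.30) lower when adjusted over the list alone, ahead of Irx3 and Hcn4. That median was 0.30 without wild-type replicate 3 and -0.24 without wild-type replicate 2.

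No member passed, over all genes or adjusted over the list alone, in the remaining lists. Their medians and camera adjusted p-values were -0.091 and 0.280 for 56 oxidative phosphorylation genes, -0.085 and 0.322 for 42 ribosomal protein genes, -0.051 and 0.981 for 20 genes of the cardiomyocyte contractile apparatus, 0.040 and 0.833 for 16 heat shock genes and -0.017 and 0.722 for 24 unfolded protein response genes. They were -0.088 and 0.604 for 18 hypoxia genes, 0.015 and 0.648 for 10 NADPH oxidase genes, -0.54 and 0.118 for 3 skeletal muscle genes, -0.23 and 0.719 for 7 adipocyte genes, and 0.15 and 0.499 for 9 Schwann cell and nerve genes. For 7 lymphatic endothelial genes they were -0.22 and 0.648, for 3 mast cell genes -0.30 and 0.266, and for 5 B and plasma cell genes -0.17 and 0.838. The median and the mean had opposite signs for contractile, unfolded protein response, immediate early, p53, antioxidant and B cell genes. Camera's direction was that of the mean except for the p53, antioxidant and B cell lists, where it was down. Of the lists too small to test, the 2 measured neutrophil genes, Csf3r and S100a9, had a median of -0.0066, and Cd28, the 1 measured T and NK cell gene, was at 0.57 (SE 0.32). Over left-out libraries Cd28 ran from 0.33 (without wild-type replicate 1) to 0.98 (without wild-type replicate 2), with an edgeR adjusted p as low as 0.0440.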

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

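Tests with the GC content and length correction, without the genes of the mitochondrial chromosome and with edgeR's older method were chosen after seeing the data. Against 12 rises and 3 falls, DESeq2 called 352 and 266, with the same 15 genes among them, limma-voom 9 and 5, and edgeR without robust estimation 7 and 4. The GC content and length correction gave 26 and 18, and an adjusted p of 0.10 gave 216 and 131. The cause of these differences was not tested. Left-out libraries gave 0 to 982 rises and 0 to 869 falls. Upper quartile factors gave 8 and 3, and a 2-fold minimum 9 and 3, all among the 15 genes. RLE factors, both other filters, the fit without mitochondrial genes and edgeR's older method kept the same 12 and 3 genes, though having no filter changed nothing and the stricter filter removed few genes. Lists called numbered 20, and 0 with an estimated correlation or by fry; RLE factors and the stricter filter gave 20, left-out libraries 16 to 21, the correction 16 and the fit without mitochondrial genes 19. The labels do not say that the replicate numbers mark pairs of mice. Same-numbered libraries deviated with correlations of -0.12, -0.076 and -0.15, and no library correlated best with its own number. So few libraries cannot exclude a pairing. With the replicate number as a block, 143 genes were higher and 92 lower, and 21 lists passed.

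None of the named genes that changed direction had passed the test, and the cause was not tested. After the GC content and length correction Myh6 was at 0.0078, Gata2 at 0.049, Rps15 at 0.059, Chordc1 at -0.029, Ttn at -0.057, and Tnks2 and Exoc6 at -0.067. Fn1 was at 0.026 in limma-voom and 0.024 with the replicate block. Over left-out libraries, with each turned value in brackets, Myh6 ran from -0.18 to 0.13 (0.13 without knockout replicate 1, 0.12 without wild-type replicate 1). Postn ran from -1.17 to 0.43 and Col3a1 from -0.55 to 0.29, both above 0 without wild-type replicate 2. Fn1 ran from -0.20 to 0.22 (0.085 and 0.0048 without knockout replicates 1 and 3, 0.0032 and 0.22 without wild-type replicates 1 and 2). Cd79b ran from -0.41 to 0.060 (without wild-type replicate 3) and Csf3r from -0.027 (without knockout replicate 1) to 0.19. Exoc6 ran from -0.018 (without knockout replicate 3) to 0.15, and was at -0.00036 without wild-type replicate 3. S100a9 ran from -0.65 to 0.60 (0.27 without knockout replicate 2, 0.60 without wild-type replicate 2). Over the other values of named genes, 3134 kept their direction and side of the threshold, 244 came past it and 74 lost it. Depth limits genes near the floor of 12 counts per library, where counting error exceeds the common coefficient of variation of 0.166.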

Other observations

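The tests of the GC content trend on the 15 genes, on Ide and on the mitochondrially encoded genes were chosen after their results were seen. So were those of the single library, of the fibroblast share and of the clock. The tests of the count without wild-type replicate 2 after correction and of the other splits were set before their own results were seen. The correction itself was chosen after seeing the data.

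Genes around Btaf1 and Ide on chromosome 19 were chosen after their values were seen, and no difference between neighbours was tested. Whether the values at this locus follow from the loss of cytoglobin was not tested either. Btaf1 (log2 fold change 1.00, SE 0.16), Cpeb3 (0.67, SE 0.16, edgeR adjusted p = 0.0773) and Ide (1.13, SE 0.17) were higher in the knockout, and only Btaf1 and Ide passed. Fgfbp3, next to Btaf1, was at 0.68 (SE 0.28, edgeR adjusted p = 0.211), and Marchf5, which lies between Cpeb3 and Ide, at 0.076 (SE 0.12). Tnks2, before Fgfbp3, was at 0.18 (SE 0.12). Beyond Ide, Kif11 was at 0.79 (SE 0.29, edgeR adjusted p = 0.174), Hhex at -0.44 (SE 0.23, edgeR adjusted p = 0.302) and Exoc6 at 0.074 (SE 0.14). Nnt, which encodes the mitochondrial transhydrogenase and was also chosen after its values were seen, was at 1032, 1006 and 1228 CPM in the knockout libraries and 549, 453 and 774 CPM in the wild-type libraries (0.88, SE 0.18, edgeR adjusted p = 0.0628). For Nnt too, whether the level follows from the loss of cytoglobin was not tested.

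Of the 10 splits of the 6 libraries into 3 and 3, the real one gave 12 rises and 3 falls, as did no other, so 1 split reached each count; the highest of the others was 0. Of the gene lists, the real split called 20 and the others from 10 to 21, so 2 splits gave as many. Camera with the preset correlation thus called many lists whatever the grouping. With 10 splits a share under 0.05 cannot be reached.

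GC content differed in its effect between libraries. Across genes, the deviation from the mean had a Spearman correlation with GC content of 0.57 and 0.48 in wild-type replicates 1 and 3, -0.27 in wild-type replicate 2, and -0.48, -0.20 and -0.38 in the knockout libraries. The 15 calls kept a median of 0.819 times their log2 fold change after the trend was removed. As their whole source the trend is argued against, since 13 of them passed after its removal. Ide moved from 1.13 (SE 0.17) to 0.91 (SE 0.19), a ratio of 0.805, and missed the threshold (edgeR adjusted p = 0.0809, against a highest value of 0.154 over 17 alternatives) through a smaller fold and a larger error, so for Ide it stays open. For the mitochondrially encoded genes, whose median went from 0.25 to 0.056, and for the 1851 calls without wild-type replicate 2, which became 367, the trend is a candidate source, and a genotype effect that itself follows GC content was not tested.

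Lower activated fibroblast genes in the knockout may rest on wild-type replicate 2, since the list's median went from -0.78 to -0.11 without it. Activated genes of that library exceeded the other wild-type libraries by a median log2 of 1.27, and 19 identity genes outside that list by 0.24 (quartiles -0.13 and 0.56). These values argue against a larger share of otherwise unchanged fibroblasts as the whole source. They cannot decide on a larger share of fibroblasts that were also activated, since identity genes may themselves change on activation. Whether that heart differed in its response to angiotensin II was not tested, and an effect of genotype on fibroblast activation stays open.

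Clock genes may reflect the time of day at which hearts were collected, since genes of the Per and Dbp limb had a median log2 fold change of 0.98 over 9 and genes of the Bmal1 limb -1.05 over 5, a difference of 2.03 in the direction that a shift of phase would give. Without wild-type replicate 1 the limbs stood at 0.67 and 0.23, a difference of 0.43, so the opposition rests on that library. The clock list still passed without it (median 0.37, camera adjusted p = 0.0448), with both limb medians above 0. Bmal1, also chosen after its values were seen, was at 12.9, 1.58 and 1.72 CPM in knockout replicates 1, 2 and 3. It was at 5.89 and 8.65 CPM in wild-type replicates 2 and 3. Nfil3 was at 12.7, 9.28 and 10.8 CPM against 8.49 and 10.1 CPM. With members this uneven, a median over 5 genes cannot decide on a shift of phase, so for the other libraries the source stays open. The GC content trend is argued against as the whole source, since the clock list had a median of 0.45 after its removal and 0.43 before (camera adjusted p = 0.0145 after). An effect of genotype on the clock stays open, and times of collection were not used here.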
